A study of Homo sapiens with 6 samples.

How the data were processed

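RNA sequencing libraries from differentiated primary human skeletal myotubes were compared, 3 transfected with control siRNA and 3 with siRNA against MondoA. Per the labels' protocols, myoblasts were grown in low-glucose medium with 10% fetal bovine serum, switched to medium with 2% serum to differentiate, transfected on day 6 and collected 3 days later, and total RNA was extracted with a column kit. The library preparation is described there only as standard for the sequencer maker. Strand setting and read layout are not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. Each library was placed in its group, and numbered, from its sample title.

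The deposited transcript tables give, per the file headers, reads for each RefSeq transcript of each library. The values show that these are estimated counts made by the authors: they sum to between 99.98 and 100.0% of the library's fully exonic alignments, are mostly not whole for genes with several transcripts, and add up to whole numbers within 0.1 for 94.3 to 94.6% of genes, so that a gene's reads were divided among its transcripts. The RPKM values beside them, per the file headers, were made by the authors by dividing those reads by transcript length and by the library's alignments. These RPKM values were used only to check the unit. The counts of raw reads and of alignments per library were taken as deposited from a summary table, as were the percentages of alignments fully or partly over exons and within introns, which are percent values per the file headers. Another 4 columns of the summary tables were not used. STAR 2.5.0c, SAMtools 1.3.1, bedtools 2.26.0 and edgeR 3.20.9 with the build GRCh38 are named per the submitters' processing notes, without their roles. The counting program and its treatment of reads shared between genes are not given in the sources used here.

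The tables held 54321 transcripts of 22596 gene symbols, of which 11073 have several transcripts and 1536 transcripts had no read in any library. Symbols turned into dates by a spreadsheet affected 123 transcripts, and 122 of them, from 25 genes, were recovered through their RefSeq accessions. Depth ranged from 31811871 to 35896794 reads in the table per library, from 43691196 to 50426762 raw reads. The design fixed before the data were examined let the transcript with the most reads stand for a gene. Because the values turned out to be estimated counts divided among transcripts, the sum over a gene's transcripts, rounded to whole numbers, became the main measure before any test was run, and the transcript with the most reads became the alternative.

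Genes were kept by the default rule of filterByExpr (a minimum count of 10 and a minimum total of 15), which left 15325. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, on counts with TMM scaling (factors from 0.991 to 1.01), with the group as the only term, and p-values were adjusted by Benjamini and Hochberg over all tested genes with a threshold of 0.05. The common dispersion was 0.000914, a biological coefficient of variation of 3.02%. Such small spread between libraries lets small changes pass, so counts at larger folds and against a minimum change of 1.2-fold are given too. Levels are CPM with SD over 3 libraries, and the SE of a log2 fold change is its size divided by the square root of the F statistic. The 5 genes fixed in advance also had an exact two-sided permutation test of log2 CPM, whose smallest p with 3 against 3 libraries is 0.1.

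The 35 gene lists were written before the data were examined, 6 of them markers of other cell types, and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and its preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, in 1 direction, and does not compare them with other genes. Named genes were MLXIP, MLX, MLXIPL, TXNIP and ARRDC4, the 10 largest increases and 10 largest decreases among genes that passed, had a mean CPM of at least 5 and did not overlap between groups, the 3 smallest p-values, and up to 4 members with the smallest adjusted p of each of the 14 lists described in detail, 71 genes in all. Another 41 genes were chosen after their values were seen. Genes of the sex chromosome Y, XIST, mitochondrial genes, small RNAs and uncharacterised loci were left out of the named genes. Of the genes the rule names, 2 are not reported here.

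Alternatives fixed before the data were examined were RLE, upper-quartile and no scaling, no filter and a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, the transcript with the most reads, a minimum fold of 1.2, other camera settings and leaving out each library in turn. Alternatives chosen after seeing the data were a correction of GC content per library (a smooth trend of each library's deviation on transcript GC content, used as an offset), leaving out genes with the word GATCATG in the 3' UTR, both together, and the list tests under upper-quartile and no scaling. GC content, length and 3' UTR sequence came from GENCODE release 29 transcripts of GRCh38, 1 per gene, matched for 15067 of the tested genes (98.4%). A scan of 16379 words of 7 bases related presence of a word in the 3' UTR to the log2 fold change in 13337 genes with an annotated 3' UTR, allowing for the length and GC content of the UTR.

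Libraries of a group differed by more than sampling noise, with chi-square per degree of freedom from 1.88 to 2.72 between siControl libraries, from 2.27 to 8.91 between siMondoA libraries and from 14.3 to 19.3 between groups, so no library was counted as a duplicate. Within its group siMondoA 2 stood apart, at 5.30 with siMondoA 1 and 8.91 with siMondoA 3, against 2.27 for siMondoA 1 with siMondoA 3. The edgeR step was tested on simulated data with the means and library sizes of these 6 libraries (siMondoA against siControl, 15325 genes, 200 of them changed): it recovered 40.3% of genes changed 1.2-fold, 76.1% of those changed 1.5-fold and 92.4% of those changed 2-fold, with 10 false calls (6.71% of calls). In the same genes with a planted GC trend and no change, 527 calls were made without the GC correction and 2 with it. With a fall planted on genes with a random word, the scan ranked that word at 1, with a z of -9.92 where the lowest without planting was -3.37. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.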

Results

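Transcript levels were measured by RNA sequencing in primary human skeletal myotubes, the multinucleated muscle cells that form when cultured myoblasts fuse. Myotubes were transfected on day 6 of differentiation with a control siRNA (siControl, 3 libraries) or with an siRNA against MondoA (siMondoA, 3 libraries), and were collected 3 days later. MondoA, encoded by MLXIP, is a transcription factor that binds DNA with its partner MLX and responds to glucose-derived sugar phosphates. The comparison asked which transcripts of differentiated muscle cells differ when MondoA is depleted. The tables held 34277851, 31811871 and 32347600 reads for siControl 1, 2 and 3, and 32407609, 33054788 and 35896794 reads for siMondoA 1, 2 and 3. The series describes the 3 libraries of each condition as biological replicates but does not say whether they came from separate donors or cultures, so p-values measure the spread between these libraries, which may be partly technical.

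MLXIP was lower in every siMondoA library. It had 836, 798 and 765 reads in siControl 1, 2 and 3, against 276, 294 and 307 reads in siMondoA 1, 2 and 3. In CPM (counts relative to library size, scaled by the TMM method), MLXIP went from 24.5 ± 0.622 (SD, n = 3) to 8.62 ± 0.220 (SD, n = 3), or 35.2% of control. The log2 fold change was -1.51 (SE 0.0533; edgeR adjusted p = 1.24e-10). The exact two-sided permutation test of its log2 CPM gave p = 0.1, the smallest that 3 against 3 libraries allow. MLXIP lies on chromosome 12 from 122078728 to 122147347 on the plus strand of GRCh38.

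The established MondoA targets TXNIP and ARRDC4, which encode related alpha-arrestin proteins that restrain glucose uptake, fell with it and were among the 3 genes with the smallest p-values. TXNIP, at chromosome 1 from 145992426 to 145996631 on the minus strand, went from 554.9 ± 5.33 to 146.2 ± 0.839 CPM (SD, n = 3), a log2 fold change of -1.92 (SE 0.0248; edgeR adjusted p = 4.02e-16). ARRDC4, at chromosome 15 from 97960703 to 97973838 on the plus strand, went from 85.7 ± 1.76 to 20.7 ± 1.31 CPM (SD, n = 3), a log2 fold change of -2.05 (SE 0.0431; edgeR adjusted p = 2.2e-13). MLX, the dimer partner of MondoA, fell slightly, from 41.7 ± 0.870 to 36.9 ± 0.427 CPM (log2 -0.18, SE 0.0364; edgeR adjusted p = 0.00201), and this call was lost when the transcript with the most reads stood for the gene (log2 -0.02, adjusted p = 0.912). MLXIPL, which encodes the related glucose sensor ChREBP, was near the detection limit at 0.509 ± 0.0865 and 0.582 ± 0.0727 CPM (log2 0.18, SE 0.250; edgeR adjusted p = 0.673). No difference in MLXIPL was detectable at this depth.

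**Figure D1:**
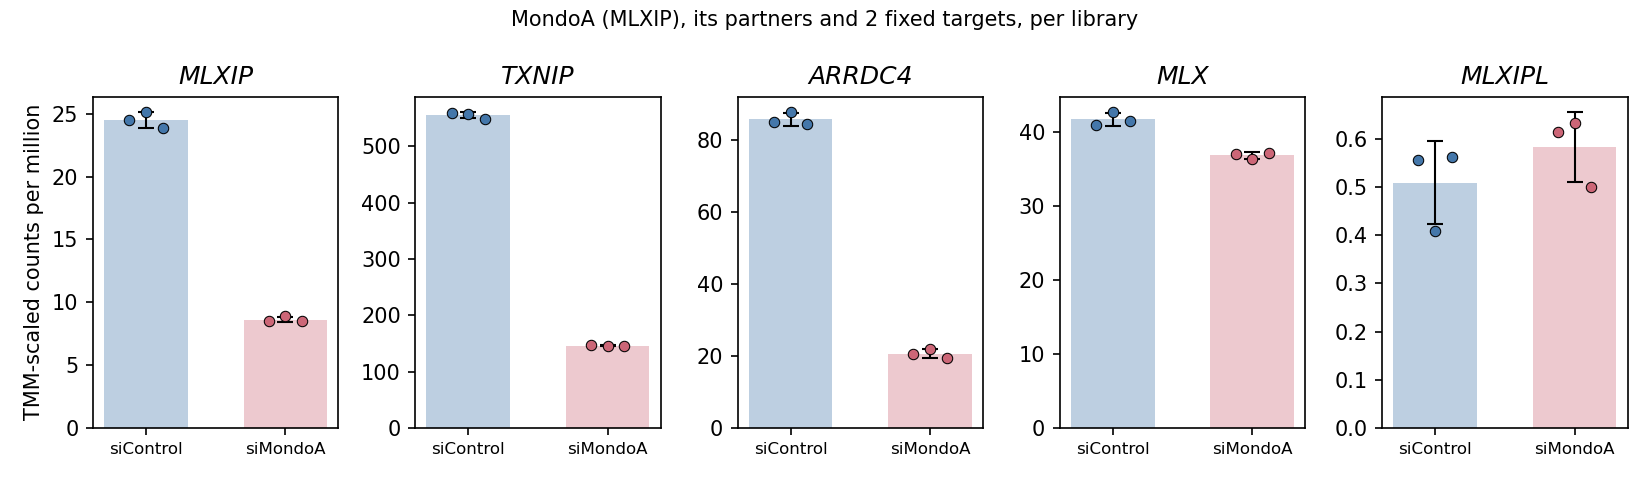
TMM-scaled CPM (vertical axis, starting at 0, a scale for each gene) of MLXIP, TXNIP, ARRDC4, MLX and MLXIPL in siControl and siMondoA libraries. Points are single libraries, bars are means and error bars are SD (n = 3); MLXIP, TXNIP, ARRDC4 and MLX lie lower in all 3 siMondoA libraries than in any siControl library, and the MLXIPL groups overlap.

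Across the transcriptome, 4281 of 15325 tested genes changed (edgeR, adjusted p below 0.05), 1974 of them higher and 2307 lower after MondoA depletion. Which direction held more genes depended on the scaling, with 2239 higher and 2056 lower under upper-quartile scaling and 2275 higher and 2025 lower by library size only. Most changes were small. The median size of the log2 fold change among these genes was 0.22, 62.5% of them changed by less than 1.2-fold, 338 changed by at least 1.5-fold (187 higher, 151 lower) and 65 by at least 2-fold (41 higher, 24 lower). When tested against a minimum change of 1.2-fold, 382 genes passed (139 higher, 243 lower). The libraries of the groups did not overlap in 6322 genes (41.3% of those tested), where chance gives 10%. With the transcript with the most reads standing for each gene, 1706 of 15018 genes changed, 677 higher and 1029 lower.

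Outside the MondoA targets, the largest decreases among genes with a mean of at least 5 CPM were in genes of varied function. RPTN, which encodes the epidermal matrix protein repetin, fell as far as TXNIP, from 44.9 ± 0.746 to 11.9 ± 0.386 CPM (SD, n = 3; log2 -1.91, SE 0.0446; edgeR adjusted p = 6.66e-13), and was the remaining gene among the 3 with the smallest p-values. CDC42SE2, a binding partner of the small GTPase CDC42, had a log2 fold change of -0.99, ADPGK, an ADP-dependent glucokinase, -0.98, the orphan nuclear receptor NR2F6 -0.95, the tubulin-binding stathmin STMN2 -0.93, the integrin activator FERMT2 (kindlin-2) -0.90 and the secreted glycoprotein OLFML2A -0.88. FERMT2 was the most abundant of these, with means of 272 and 146 CPM (n = 3; log2 -0.90, SE 0.0254). With ARRDC4, TXNIP and MLXIP these were the 10 largest decreases among genes that passed, had a mean of at least 5 CPM and did not overlap between groups. Of these 10, 7 carry the 7-base word GATCATG in the 3' UTR, namely ARRDC4, MLXIP, NR2F6, STMN2, FERMT2 and OLFML2A with 1 copy each and ADPGK with 3, whereas among all tested genes with an annotated 3' UTR 1249 of 13337 carry it. The word was picked from a scan of these same fold changes, and MLXIP is the target of the siRNA. The count is therefore not independent evidence for the word.

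Among genes that passed, had a mean of at least 5 CPM and did not overlap between groups, genes induced by type I interferon made up 7 of the 10 largest increases. Of the 10, C1QL4, a secreted C1q-related protein outside that group, rose most, from 8.71 ± 0.205 to 20.3 ± 1.01 CPM (SD, n = 3; log2 1.22, SE 0.0590; edgeR adjusted p = 2.91e-09). Next came the carboxypeptidase CPA4 (log2 1.03) and the fibronectin-domain protein FNDC1 (log2 1.02), also outside it. FNDC1 varied within its group, at 12.3, 19.0 and 12.4 CPM in siMondoA 1, 2 and 3. The remaining 7 were OAS2 (log2 1.02), ISG15 (0.99), IFIT1 (0.95), IFI6 (0.87), IFIT2 (0.86), OAS3 (0.83) and MX1 (0.79), all products of the antiviral interferon response. MX1 passed with edgeR (adjusted p = 0.00255) but not with DESeq2 (adjusted p = 0.0572) or with the transcript with the most reads (adjusted p = 0.129).

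The list of interferon-response genes rose almost as a whole. Of its 27 tested members 25 rose and none fell, by the adjustment over all genes and when adjusted over the list alone, with a median log2 fold change of 0.71 (camera adjusted p = 5.77e-10). This set call was lost when the correlation between members was estimated (adjusted p = 0.429 with an estimated correlation). IFI6, which encodes a mitochondrial antiviral protein, went from 83.8 ± 8.01 to 152.9 ± 25.1 CPM (SD, n = 3; log2 0.87, SE 0.0900; edgeR adjusted p = 6.06e-06). Transcripts of the RNA-binding IFIT proteins also rose, with log2 fold changes of 0.95 for IFIT1, 0.86 for IFIT2 and 0.71 for IFIT3. The members that did not pass were ISG20 (log2 -0.39, SE 0.233) and TLR3 (log2 0.07, SE 0.110). Both groups had been transfected with siRNA.

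Genes of the contractile apparatus were lower after MondoA depletion. Of 41 tested genes of the sarcomere and of excitation-contraction coupling 24 fell and 4 rose (26 and 5 when adjusted over the list alone), with a median log2 fold change of -0.16 (camera adjusted p = 1.85e-05; adjusted p = 0.429 with an estimated correlation). TPM3, a slow-fibre tropomyosin, went from 672.1 to 420.0 CPM (log2 -0.68, SE 0.0257; edgeR adjusted p = 2.45e-10), and the myosin-binding protein MYBPC1 from 128.0 to 69.7 CPM (log2 -0.88, SE 0.0346; edgeR adjusted p = 3.70e-10). TRDN, the calcium-release protein triadin, and MYL2, a slow and cardiac myosin light chain, had log2 fold changes of -0.57 and -0.52. The members that rose were the fast troponin TNNI2 (log2 0.23), the calcium-release channel RYR1 (0.14), the calcium channel subunit CACNA1S (0.13) and myoglobin MB (0.98, at 0.480 and 0.948 CPM).

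Myosin heavy chain genes fell in the same comparison, 7 of 8 tested and none higher, with the same counts when adjusted over the list alone. Their median log2 fold change was -0.42 (camera adjusted p = 1.85e-05; adjusted p = 0.268 with an estimated correlation). The fast IIa isoform MYH2 went from 733.1 to 406.8 CPM (log2 -0.85, SE 0.0236; edgeR adjusted p = 5.92e-12), and the slow isoform MYH7 had a log2 fold change of -0.46, MYH6 -0.56 and the perinatal MYH8 -0.29. MYH13, at 0.718 and 0.769 CPM, did not pass. These genes are near-identical in sequence over long stretches and how shared reads were assigned is not given in the sources used here, so values of single isoforms are uncertain. None of the members of either contractile list carries the word GATCATG in its 3' UTR.

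Several regulators of myogenesis rose, and the list passed fry but not camera. Of 19 tested genes 9 rose and 1 fell, with the same counts when adjusted over the list alone, and the median log2 fold change was 0.11 (camera adjusted p = 0.0731, fry adjusted p = 0.0246). CDKN1C, the cell cycle inhibitor p57, went from 26.3 to 40.9 CPM (log2 0.64, SE 0.0521; edgeR adjusted p = 5.74e-07), the muscle cadherin CDH15 from 142 to 182 CPM (log2 0.36) and the transcription factor SRF had a log2 fold change of 0.21. MEF2C, a transcription factor of muscle differentiation, was the member that fell (log2 -0.18). With the transcript with the most reads 4 of 18 members rose, and the SRF and MEF2C calls were lost (adjusted p = 0.526 and 0.0508). With the GC correction 7 rose and 3 fell.

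Genes of the extracellular matrix and of TGF-beta signalling were higher. Of 40 tested 23 rose and 6 fell (25 and 8 when adjusted over the list alone), with a median log2 fold change of 0.13 (camera adjusted p = 0.00116; adjusted p = 0.404 with an estimated correlation). The basement membrane collagen COL4A2 went from 319.9 to 391 CPM (log2 0.29, SE 0.0254; edgeR adjusted p = 1.26e-06). Elastin ELN had a log2 fold change of 0.36, the collagen cross-linking oxidase LOXL2 0.27 and the matricellular growth factor CTGF 0.30.

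Among metabolic genes, those of fatty acid and cholesterol synthesis were lower. Of 18 tested genes of fatty acid synthesis 9 fell and 3 rose (9 and 4 when adjusted over the list alone), with a median log2 fold change of -0.18 (camera adjusted p = 0.0343; adjusted p = 0.404 with an estimated correlation). The members with the smallest p-values were desaturases and an elongase: FADS1 (log2 -0.52, SE 0.0339; edgeR adjusted p = 6.12e-08), FADS2 (-0.53), the stearoyl-CoA desaturase SCD (-0.47, from 250.4 to 181.2 CPM) and ELOVL5 (-0.38), of which FADS1 and ELOVL5 carry the word GATCATG in the 3' UTR. The members that rose were the mitochondrial citrate carrier SLC25A1 (log2 0.24), malonyl-CoA decarboxylase MLYCD (0.32), which breaks down the precursor of synthesis, and the elongase ELOVL1 (0.14). Of 25 genes of the cholesterol synthesis list 11 fell and 2 rose (12 and 2 when adjusted over the list alone), with a median log2 fold change of -0.10 (camera adjusted p = 0.00640; adjusted p = 0.646 with an estimated correlation). The pathway enzymes IDI1 and FDPS had log2 fold changes of -0.28 and -0.20. The members that rose were LSS (log2 0.11) and the regulator SREBF2 (0.17). Without siMondoA 2 neither list passed (camera adjusted p = 0.0515 for both), and fatty acid synthesis was also lost without siControl 1 (0.0515), without siMondoA 1 (0.0579), with genes of CPM of at least 1 in 3 libraries (0.0531) and without genes carrying the word (median -0.11, camera adjusted p = 0.127). With the transcript with the most reads, 2 genes of cholesterol synthesis fell and 1 rose and the list did not pass (camera adjusted p = 0.122). In that setting 6 genes of fatty acid synthesis fell and the calls of the 3 members that rose were lost, while this list passed (camera adjusted p = 0.0207).

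Genes of glycolysis, glycogen metabolism and the tricarboxylic acid cycle were slightly lower as lists. Of 24 tested glycolysis genes 10 fell and 2 rose, with the same counts when adjusted over the list alone and a median log2 fold change of -0.07 (camera adjusted p = 0.0413; adjusted p = 0.929 with an estimated correlation). PFKM, the muscle phosphofructokinase, went from 122 to 79.7 CPM (log2 -0.62, SE 0.0374; edgeR adjusted p = 2.96e-08) and carries GATCATG in its 3' UTR, while PGK1 had a log2 fold change of -0.30 and the lactate dehydrogenases LDHA and LDHB -0.20 each. The members that rose were hexokinase HK2 (log2 0.25) and the muscle enolase ENO3 (0.09). Of 20 genes of glycogen metabolism 6 fell and 2 rose (7 and 2 when adjusted over the list alone), with a median log2 fold change of -0.07 (camera adjusted p = 0.0413; adjusted p = 0.929 with an estimated correlation). The phosphorylase kinase subunits PHKG1 and PHKA1 had log2 fold changes of -0.55 and -0.44 (PHKA1 carries GATCATG in its 3' UTR), the glycogen-targeting phosphatase subunit PPP1R3A -0.78 (5.93 to 3.43 CPM) and the branching enzyme GBE1 -0.20, whereas GYG2 (0.12) and PPP1R3C (0.10) rose. Of 22 genes of the tricarboxylic acid cycle 6 fell and 1 rose (7 and 1 when adjusted over the list alone), with a median log2 fold change of -0.05 (camera adjusted p = 0.0480; adjusted p = 0.557 with an estimated correlation). DLST, a 2-oxoglutarate dehydrogenase subunit that carries GATCATG in its 3' UTR, had a log2 fold change of -0.46, SUCLA2 -0.25, FH -0.15 and SDHA -0.13, and the anaplerotic carboxylase PC rose (0.16). Of 18 alternative settings, 10 ended the call for glycolysis, 11 for glycogen metabolism and 15 for the tricarboxylic acid cycle. Leaving out genes with the word was among these settings for each list (camera adjusted p = 0.0667, 0.0667 and 0.127, in this order). With the GC correction as well, glycolysis passed (0.00488), while glycogen metabolism (0.0696) and the tricarboxylic acid cycle (0.11) did not.

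Antioxidant and cell cycle genes were lower as lists. Of 25 genes of the NRF2 and thioredoxin systems 11 fell and 1 rose (14 and 3 when adjusted over the list alone), with a median log2 fold change of -0.08 (camera adjusted p = 0.00479; adjusted p = 0.404 with an estimated correlation). The mitochondrial peroxidase PRDX3 went from 104 to 57.1 CPM (log2 -0.86, SE 0.0344; edgeR adjusted p = 3.77e-10) and has 2 copies of GATCATG in its 3' UTR, and SLC7A11, the cystine transporter, has 1 (log2 -0.45). The quinone reductase NQO1 (-0.33) and the thioredoxin reductase TXNRD1 (-0.25), which do not carry it, also fell, and TXN2, the mitochondrial thioredoxin, rose (0.19). Once genes with the word were left out, the median of the remaining 20 members was -0.07 and the list did not pass (camera adjusted p = 0.0667), but it passed when the GC correction was made as well (median -0.07, camera adjusted p = 0.00996). Of 36 cell cycle genes 11 fell and 2 rose, with the same counts when adjusted over the list alone and a median log2 fold change of -0.10 (camera adjusted p = 0.00719; adjusted p = 0.404 with an estimated correlation). TYMS, thymidylate synthase, had a log2 fold change of -0.71 (9.26 to 5.66 CPM) and carries the word, and the replication helicase subunits MCM5 and MCM7 had -0.35 and -0.22, whereas cyclin CCND1 (0.20) and the licensing factor CDC6 (0.28) rose.

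The lists built around MondoA itself did not pass camera. Of 15 tested glucose-responsive genes ascribed to MondoA or ChREBP 4 fell and 4 rose, with the same counts when adjusted over the list alone (median log2 fold change -0.07, camera adjusted p = 0.773). Fry gave this list as lower (adjusted p = 0.000436). The list includes TXNIP and ARRDC4, at 26.4% and 24.1% of control, and its mean log2 fold change was -0.25. The fry result may therefore rest largely on these genes rather than on the list as a whole. Besides TXNIP and ARRDC4, the transcription factors KLF10 (log2 -0.20) and KLF11 (-0.34) fell. TKFC, an enzyme of fructose metabolism (0.33), the glucose-6-phosphatase G6PC3 (0.29), HK2 (0.25) and the pyruvate dehydrogenase kinase PDK4 (0.35) rose. Of 13 genes of the MYC, MAX and MLX network 3 rose and 3 fell (4 and 3 when adjusted over the list alone). MYC (log2 0.25), MAX (0.22) and MXD4 (0.13) rose, and MLXIP, MLX and MXI1 (-0.12) fell. Its median was -0.00 and its mean -0.08, while camera gave the direction as higher (adjusted p = 0.975) and fry as lower (adjusted p = 0.00645). The list includes MLXIP, the target of the siRNA (log2 -1.51), so the fry result is not independent of the knockdown itself.

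In all, 11 of 35 lists passed camera with its preset correlation, 18 passed fry and 0 passed camera with an estimated correlation. With that estimate, 3 of the 35 lists had an unadjusted camera p below 0.05. The number passing fell to 7 without siControl 1, to 7 without siMondoA 1 and to 6 without siMondoA 2. It was 6 when genes with the word GATCATG were left out, 11 with the GC correction and 9 with both. With the GC correction autophagy and lysosome passed (camera adjusted p = 0.0148) and the tricarboxylic acid cycle did not (0.0520). With the transcript with the most reads standing for each gene, fewer members were called: 3 cell cycle genes, 2 of the tricarboxylic acid cycle and 3 of glycogen metabolism fell, and 15 of the extracellular matrix list and 17 of the interferon list rose. In this setting the calls of G6PC3, PHKG1, PHKA1, IDI1, FDPS, DLST, FH, SDHA and MCM7 were also lost, as were those of RYR1, MB, ELOVL1, MLYCD, SLC25A1, LSS, ENO3, PPP1R3C, PDK4, TXN2, CDC6, MXD4 and MXI1. The calls of GYG2 and PC were lost with DESeq2 (adjusted p = 0.138 and 0.0700). Members named to complete a count of 5 or fewer were chosen after their values were seen.

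**Figure D2:**
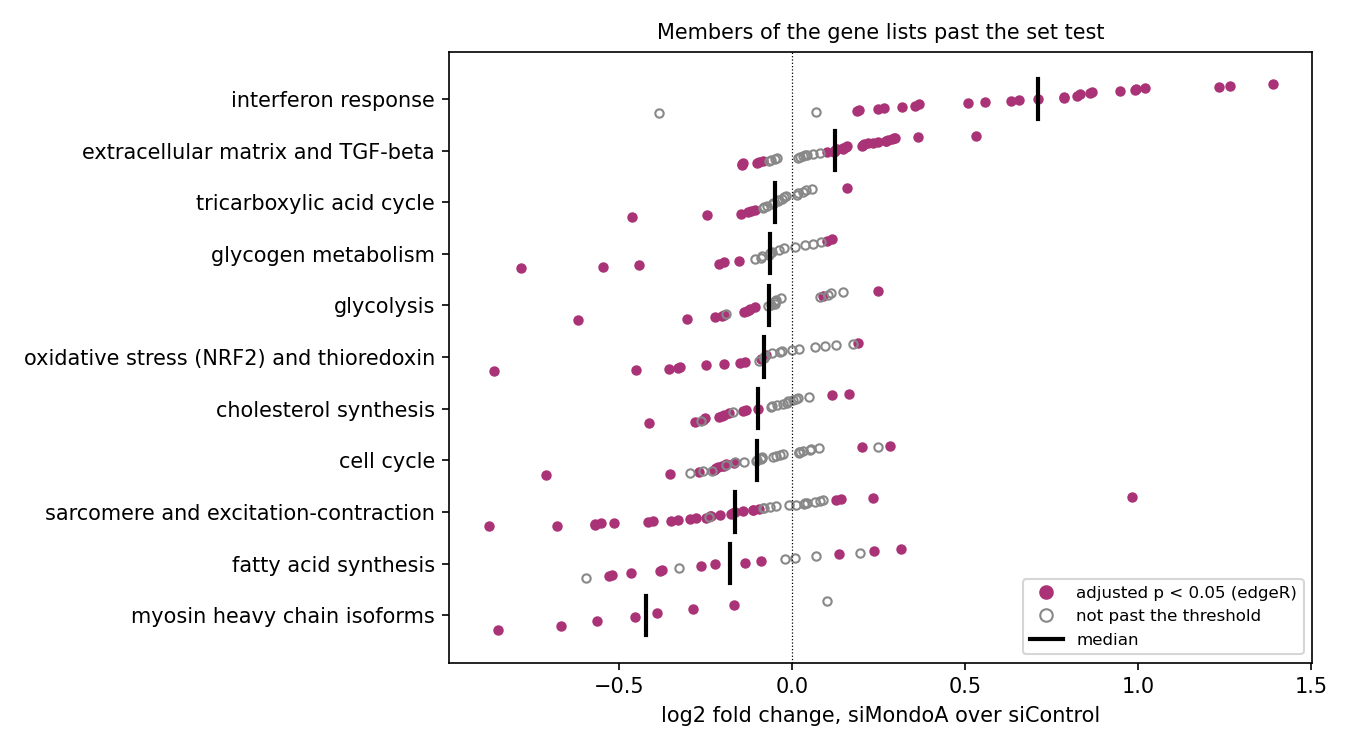
Log2 fold change, siMondoA over siControl (horizontal axis), of each tested member of the 11 gene lists past the set test. Points are genes, filled where the edgeR adjusted p is below 0.05 and open otherwise, and black bars are list medians, from -0.42 for the myosin heavy chains to 0.71 for the interferon response.

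Some measured properties moved with the siRNA given. Fold changes followed the GC content of the transcript, with a Spearman correlation of 0.253 across 15067 genes, which are not independent replicates. In the eighth of genes with the lowest GC content 26.1% fell and 6.85% rose, and in the eighth with the highest 5.73% fell and 23.9% rose. The word GATCATG was present in the 3' UTR of 442 of 2214 genes that fell (19.96%), 102 of 1819 that rose (5.61%) and 705 of 9304 that did not pass (7.58%). Because the word was picked from a scan of these same fold changes, these shares are not independent evidence for it. Reads within introns took 10.8 to 11.5% of alignments in siControl and 11.8 to 13.2% in siMondoA libraries, with siMondoA 2 highest. A set of 5 small RNA genes chosen by name took 8.01 ± 0.351% of reads in siControl and 9.07 ± 0.432% in siMondoA libraries (SD, n = 3). Transcripts of the mitochondrial chromosome took 0.0631 to 0.0679% of reads in siControl and 0.0816 to 0.0866% in siMondoA libraries.

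**Figure D3:**
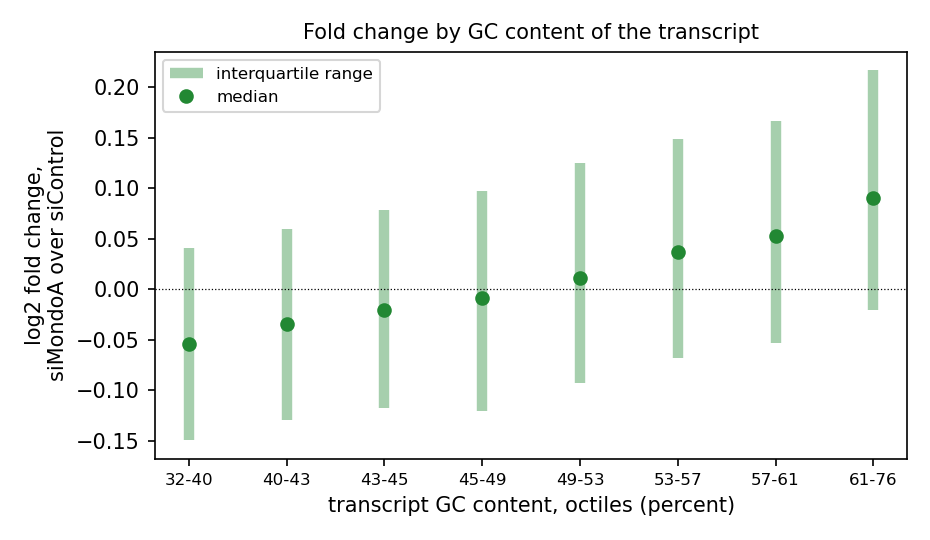
Log2 fold change, siMondoA over siControl (vertical axis), of tested genes in 8 classes of transcript GC content in percent (horizontal axis). Points are medians, from -0.05 in the lowest to 0.09 in the highest class, and bars span the interquartile range.

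**Figure D4:**
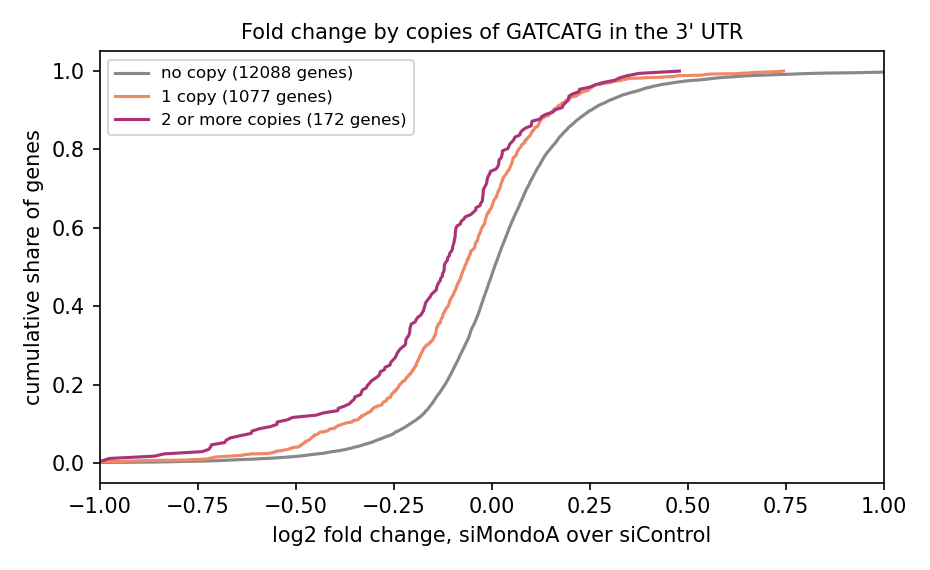
Cumulative share of genes (vertical axis) by log2 fold change, siMondoA over siControl (horizontal axis, drawn from -1 to 1), for genes with no copy (12088 genes), 1 copy (1077) or at least 2 copies (172) of the word GATCATG in the 3' UTR. The medians are 0.01, -0.07 and -0.12.

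Lists of markers of other cell types did not pass camera. Of 8 tested immune markers 0 changed with edgeR (2 at an unadjusted p below 0.05), 0 with DESeq2 and 0 with limma-voom, and their median log2 fold change was 0.01 with a mean of 0.15 (camera adjusted p = 0.845). The other marker lists also failed camera, with adjusted p = 0.845 for fibroblast markers (4 rose and 4 fell of 16, median 0.01, 5 and 5 when adjusted over the list alone), 0.778 for adipocyte markers (1 rose of 7, median 0.03, the same when adjusted over the list alone), 0.845 for smooth muscle and pericyte markers (3 rose and 4 fell of 13, 4 and 4 when adjusted over the list alone, median 0.08 and mean -0.02), 0.845 for endothelial markers (1 rose and 1 fell of 6, median 0.08, likewise over the list alone) and 0.838 for markers of undifferentiated myoblasts (3 rose and 4 fell of 13, median -0.03, likewise over the list alone). Fry gave the myoblast markers as lower (adjusted p = 0.0342) and passed none of the other marker lists.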

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

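The tests of transcript length and of immune markers, and the GC correction, were chosen only after the result was seen.

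Alignments within introns and partly over exons, which no comparison of genes used, took a larger share in every siMondoA library than in any siControl library. Introns took 11.9%, 13.2% and 11.8% of alignments in siMondoA 1, 2 and 3, against 10.8 to 11.5% in siControl. Alignments partly over exons took 0.415%, 0.424% and 0.410% in siMondoA 1, 2 and 3, against 0.400 to 0.407% in siControl. No explanation was tested for these shares.

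The many small changes followed the GC content of the transcript. Single libraries differed in this trend, with Spearman correlations of each library's deviation with GC content of -0.0809, -0.259 and -0.224 in siControl and 0.176, 0.00487 and 0.377 in siMondoA. A GC difference between libraries as the whole cause is argued against by the correction per library, after which 79.7% of the genes changed were still called in the same direction, although the trend itself was removed. The correlation with transcript length was -0.0381, far below that with GC content, and the trend did not rest on 1 library, since the smallest correlation with a library left out was 0.178 (without siMondoA 3). Whether the trend comes from handling of the libraries or from loss of MondoA stays open, since the labels give no batch and an effect of MondoA on it was not tested.

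Interferon-stimulated genes were higher in siMondoA libraries although both groups were transfected with siRNA. RNA from immune cells is argued against by the immune marker list, with a median log2 fold change of 0.0102: its tested members other than CD68, the most abundant, summed to 4.22 CPM in siControl and 4.43 CPM in siMondoA libraries, while interferon-response genes went from 872 to 1176 CPM. GC content did not account for the rise (median 0.744 after the GC correction, 0.71 without it), nor did a single library (at least 24 of the 25 members called stayed called with any library left out). Its size did vary, with a median from 0.548 (without siControl 3) to 0.785 (without siMondoA 2). A reaction to the siRNA duplex and an effect of losing MondoA cannot be told apart, because the design has 1 group given a siRNA against MondoA. Both remain hypotheses.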

How the results depend on the processing

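The GC correction, leaving out genes with the word GATCATG, both together, and the list tests under upper-quartile and no scaling were chosen only after the result was seen. MLXIP stayed between -1.55 and -1.49 (log2) in all 16 alternatives. The count of genes changed stayed within 1.5 times of 4281 except with the transcript with the most reads (1706, with 677 higher and 1029 lower) and against a minimum change of 1.2-fold (382, fewer by construction). DESeq2 gave 1251 genes higher and 29 changed at least 2-fold. The count at least 2-fold was 105 without a filter on low counts and 36 with CPM of at least 1 in 3 libraries. Lists past the set test numbered 0 with an estimated correlation, 18 with fry, 7 with the CPM filter, 6 without genes carrying the word (9 with the GC correction as well), and 6 (without siMondoA 2) to 13 (without siMondoA 3) with a library left out. Under fry the MYC, MAX and MLX network was lower (median log2 -0.0015, adjusted p = 0.00645) where camera had it higher. That list includes MLXIP, the target of the siRNA. With a library left out, TLR3 ranged from -0.00 (-0.0050) to 0.11 and MYH13 from -0.0278 to 0.34 without passing. Beyond construction, the cause was not tested.

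Of 70 genes named by the rule besides MLXIP, 13 lost their call with the transcript with the most reads, FH and SDHA also with a library left out and MX1 with DESeq2, and the others lost no call where they were tested. Of 41 genes chosen later, 16 lost a call in some setting, 14 of them with the transcript with the most reads and 9 with a library left out. With simulated libraries of this depth and number and 200 genes changed, 40.3% of 1.2-fold changes were recovered. With 4281 genes called in the real data, adjustment over all genes is less strict, so this share need not apply there. With the replicate number as a replicate block, 4238 genes changed and 8 lists passed, glycogen metabolism, glycolysis and the tricarboxylic acid cycle being lost (adjusted p = 0.0585, 0.0610 and 0.0799). Deviations of same-numbered libraries correlated at -0.0190, 0.0202 and 0.0282, so no pairing by number was visible. A shared culture or day cannot be excluded by this, because the deviations also hold counting noise. The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 4281 genes changed, 1974 higher, 2307 lower and 65 at least 2-fold, against at most 0 in the others (edgeR, up to 436 at an unadjusted p below 0.05, 0 with limma-voom), and 11 lists against at most 6. Each other split mixes siControl and siMondoA libraries, so the difference between the groups adds to the spread and lowers the calls. Their counts therefore do not show what chance alone would give.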

Other observations

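All tests of the 3' UTR word and the GC correction were chosen only after the result was seen, and the gene families were not fixed before the data were examined. The genes named here were chosen after their values were seen, except where the report names them.

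Lists not described so far held marked changes of single genes. Of 30 autophagy and lysosome genes 12 fell and 4 rose (the same adjusted over the list alone; median log2 fold change -0.06, camera adjusted p = 0.0530). The list passed camera with the GC correction (adjusted p = 0.0148, 10 lower and 1 higher), with that correction and the genes with the word left out (0.0457), and without siMondoA 3 (0.0323). These passes used the preset correlation, and with an estimated correlation and all libraries camera gave an adjusted p = 0.429. Among the members that fell were the autophagosome proteins MAP1LC3B (log2 -0.70, with GATCATG in its 3' UTR) and GABARAPL1 (-0.33) and the protease CTSL (-0.34). In fatty acid uptake and oxidation 4 of 28 rose and 5 fell (5 and 7 adjusted over the list alone; median -0.01, mean 0.04 and camera direction lower, adjusted p = 0.960): the thiolase ACAA2, which carries the word, had a log2 fold change of -0.72, and ANGPTL4, an inhibitor of lipoprotein lipase, rose from 1.22 to 2.43 CPM (1.00). Triglyceride synthesis gave 4 higher and 4 lower of 18 (the same over the list alone; median 0.02, adjusted p = 0.845), with the acyl-CoA synthetases ACSL4 (-0.44, with the word) and ACSL1 (-0.36) lower. In mitochondrial biogenesis 4 rose and 5 fell of 20 (the same over the list alone; median 0.01, camera direction lower, adjusted p = 0.907), with the coactivator PPARGC1A at -0.46. In glucose transport and insulin signalling 6 rose and 8 fell of 30 (10 and 9 over the list alone; median 0.04, mean -0.01 and camera direction higher, adjusted p = 0.845), with the insulin receptor substrate IRS2 higher (0.50, with the word) and the glucose transporter SLC2A4 lower (-0.85, from 1.86 to 1.03 CPM). Muscle protein breakdown gave 5 higher and 5 lower of 19 (the same over the list alone; median -0.06, adjusted p = 0.845), with the ubiquitin ligase genes FBXO40 at -1.11 and FBXO32 at -0.22, the latter lost with the transcript with the most reads.

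In the remaining lists, p53 targets gave 3 higher and 6 lower of 22 (4 and 7 over the list alone; median -0.04, adjusted p = 0.441), with the cell cycle inhibitor CDKN1A at -0.50. Stress response and amino acid genes under ATF4 gave 6 higher and 4 lower of 27 (7 and 5 over the list alone; median 0.04, adjusted p = 0.591), with the amino acid transporter SLC7A5 at 0.43. Inflammation genes gave 2 higher and 3 lower of 20 (the same over the list alone; median 0.02, adjusted p = 0.845), with the cytokine LIF at 0.42. Nuclear-encoded oxidative phosphorylation gave 0 higher and 8 lower of 50 (0 and 5 over the list alone; median -0.02, adjusted p = 0.191, or 0.0262 without siMondoA 3). The others did not pass camera either: lipid droplets (5 higher and 4 lower of 15, the same over the list alone, median -0.01, mean 0.03 and camera direction higher, adjusted p = 0.907), the pentose phosphate pathway (3 and 5 of 10, the same over the list alone, median -0.06, adjusted p = 0.845), the unfolded protein response (6 and 6 of 24, 8 and 7 over the list alone, median 0.02, adjusted p = 0.907), hypoxia targets (6 and 6 of 22, 6 and 7 over the list alone, median 0.02, camera direction lower, adjusted p = 0.907) and the circadian clock (1 and 3 of 18, the same over the list alone, median -0.01, adjusted p = 0.907). Of the lists in this and the preceding paragraph, fry gave autophagy and lysosome (adjusted p = 0.00133), p53 targets (0.000771), fatty acid uptake and oxidation (0.0422) and the pentose phosphate pathway (0.0421) as lower. With the transcript with the most reads, each list in these paragraphs had fewer members called, as in autophagy and lysosome, where 7 fell. Among fibroblast markers COL1A1 rose (0.53) and S100A4 fell (-0.37).

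The word GATCATG was more frequent in the 3' UTRs of genes that fell, and of 16379 words scanned it had the lowest z (-13.7, followed by TGATCAT at -9.43). The lowest z among 629 other words of the same base composition was -4.36, for GGATCAT, which overlaps GATCATG. Every z already allowed for GC content and length of the 3' UTR, so the word stood out beyond the fitted trends. The comparison with other words is therefore not a separate test of GC content or length. The next base was used to ask about Alu repeats. Genes with a copy followed by A had a median log2 fold change differing by -0.0639 (95% interval -0.0958 to -0.0296, permutation p = 9e-05) from that of genes with all copies followed by C, the base found in Alu. The medians were -0.108 and -0.0443, against 0.00637 for genes with no copy. This cannot decide on Alu repeats. Genes in the first group may hold several copies, and GC content and length of the 3' UTR were not allowed for. A candidate explanation is pairing of the word with the seed of the MondoA siRNA, an off-target effect. Genes with at least 2 copies differed in the median from genes with 1 copy by -0.0521 (95% interval -0.0827 to -0.0200, permutation p = 0.00416). That difference cannot decide on the seed, because GC content and length of the 3' UTR were not allowed for in it. MLXIP itself holds the word at chromosome 12 of GRCh38 from 122135252 to 122135258 in the coding sequence (exon 10 of 17) and from 122144535 to 122144541 in the 3' UTR (exon 17). The siRNA sequence was not used here, so pairing with its seed remains a hypothesis, and an effect of losing MondoA on the same genes was not tested.

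Among 243 families of genes grouped by symbol, 1 passed camera, the MYH myosins, which include nonmuscle MYH9 (0.17) and MYH10 (-0.56) beside the muscle isoforms already described (13 tested, 8 lower and 1 higher, median log2 fold change -0.34, adjusted p = 0.00498; adjusted p = 0.992 with an estimated correlation). With an estimated correlation 0 families passed, 3 having an unadjusted p below 0.05. With the GC correction 2 passed, the MYH myosins and the histone genes (67 tested, 8 lower and 1 higher without the correction; median -0.12 and adjusted p = 0.0315 with it).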
